A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

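NRF1 ChIP-seq was made in mouse embryonic stem cells of the 129P2/OlaHsd background with a polyclonal NRF1 antibody, in 4 samples with 1 library each, per the labels. The labels also describe 3 DNase-seq samples, from mouse embryonic stem cells, human embryonic stem cells and pancreatic islet, for the last of which they disagree on the species. These were not analysed here. The eighth sample is a SLOT reporter library in mouse embryonic stem cells. Each group had 1 library, so no test between samples was possible. The submitters' processing notes name BWA and the builds mm10 and hg19, with no version or role.

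The authors deposited 1 table of binding events for the 4 ChIP-seq samples together, in mm10 coordinates, made with the GEM event caller per the deposited table's own name; the version is not given in the sources used here. Per the file headers it gives an estimated count of ChIP reads per event, which need not be whole and is summed over the samples the caller pooled. The deposited signal column holds the background reads the caller expected at the event. The deposited q-value is on a −log10 scale, runs from 2.01 and is capped at 999, which 3309 events reached. The deposited noise fraction was 0 in 83.7% of events and was not used further. The deposited score of the k-mer group was not used further, and the k-mer itself was taken as listed. The 3 columns for a control library hold no value, so no fold over a control could be had, and regions that attract reads in any library are not removed by it. The read total in events is 5528702.7; library totals were not used here. Reads from PCR-amplified libraries are not independent molecules, so intervals cover counting error only.

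The SLOT table that the authors deposited has a sequence and a score per line, with no read count, replicate or label. The unit and the making of this score are not given in the sources used here. Inserts between the constant flanks were taken as the unit, with the median score where an insert occurred in several sequences (4868 inserts). In the 3350 inserts found in at least 3 sequences, the score varied by a median of 2.15% (coefficient of variation). The 24070 sequences without these flanks, with a median score of 326.1, entered the range, the single-base pairs and the alternative that uses all sequences.

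Gene positions came from RefSeq for GRCm38.p6, the assembly also called mm10, which as used here has gene spans without strand. The planned distance to a transcription start site was therefore replaced by the distance to either end of a gene. Lists of 464 names matched 451 protein-coding genes after older and newer symbols of the same gene were merged, with 0 names unmatched. Shares have 95% Wilson intervals, and a share of 0 is given with the limit of 3 counts. Lists were tested with a two-sided Fisher's exact test against all other protein-coding genes, and motifs with a two-sided permutation test of the difference in medians of log2 score (100000 permutations), both with Benjamini-Hochberg adjustment at 0.05. Motif matches were exact on either strand and motifs in under 10 inserts were left out. Bootstrap intervals used 1000 draws, or 2000 for pairs of sequences. Variance explained came from ridge regression (penalty 1) on 70% of groups of inserts with the same first 20 bases. No reference genome was used, so the planned test of the NRF1 consensus against flanking sequence was replaced by a description of the caller's k-mers, and no model with promoter CpG count was fitted.

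By a rule written before the data were examined, the text names the 10 events with the most reads within 1 kb of a protein-coding gene, in each list the 3 genes with the strongest events and up to 2 without an event in alphabetical order, the 5 highest and 5 lowest SLOT scores, and every motif tested. One gene that this rule takes is not reported here. Gene lists, motifs and the first set of alternatives were fixed at the same time. These were windows of 500 bp and 5 kb, a −log10 q of at least 10, protein-coding genes alone, means in place of medians, separate comparison below and above the median GC content, repeated matches, and a rank correlation given GC. Those added after seeing the data were events of 50 reads or more, events with a k-mer, leaving out the 2 clusters, chromosomes 2 and 9 or Olfr genes, all sequences with their own score, inserts in 2 or more sequences, and 1 insert per shared first 20 bases.

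The list test, the distance to a gene end, the test of medians, the correlation and the search for single-base pairs were tested on simulated data. Other steps, among them the comparison within parts by GC content and the ridge regression, were not. In 50 simulations of the list test on 21900 genes, 91% of 4 lists raised from 30% to 60% were called, and 1.5% of the other lists. On 37481 inserts with shuffled scores, a log2 shift of 0.5 in 5 motifs was called in 100% of cases in 5 simulations, with a mean estimate of 0.55. In the same simulations 12% of the other motifs were called. Motifs that share inserts with a shifted motif can take up part of its shift. When no motif was shifted, 0 of 100 tests were called. Shuffling removes the likeness of scores among related inserts, so these simulations do not show how often such likeness leads to false calls. All 200 planted single-base pairs were found. Computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0, scikit-learn 1.9.0 and Matplotlib 3.10.9.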

Results

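The series covered 8 samples, each the single library of its group. NRF1, nuclear respiratory factor 1, is a transcription factor known to bind GC-rich promoters of mitochondrial and other housekeeping genes. It was profiled by ChIP-seq in mouse embryonic stem cells in 4 samples labelled nodox, dox, sr3 and sr8, names that the labels do not define. DNase-seq was made in 3 samples, which were not analysed here. SLOT, a reporter assay that tests many DNA sequences in mouse embryonic stem cells, gave 1 library. The title names a synergistic model that predicts DNase I accessibility from DNA sequence, so binding of NRF1 and the dependence of the SLOT score on factor sites were the questions taken up. The NRF1 table held 18862 binding events with 5528702.7 estimated reads, merged over the 4 samples. The SLOT table held 81873 sequences with 1 score each and no read count, so its depth is unknown. With 1 library per group there was no replicate error, and intervals below cover counting or resampling error within each table only.

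NRF1 events lay close to genes more often than random positions did. Of 18862 events, 51.4% (95% Wilson interval 50.7 to 52.2) were within 1 kb of an end of an annotated gene, against 6.44% ± 0.144 (SD, 10 sets) of random positions on the same chromosomes, a 7.98-fold difference. The share was 46.1% for protein-coding genes alone and 44.2% within 500 bp of any gene. Among events within 1 kb of a protein-coding gene, the one with the most reads lay 55 bp outside Ehmt1, a histone H3 lysine 9 methyltransferase, with 11902 reads. Upf1, the helicase of nonsense-mediated mRNA decay, had a pair of events among the first 10 of that set, with 9208 and 8012 reads. Over all events, including those far from genes, Ehmt1 ranked 33 and the Upf1 events 40 and 51. Either end of a gene counted, because the annotation used gave no strand, so the share includes events at 3′ ends.

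The other events among the 10 with the most reads near protein-coding genes, in mm10 coordinates, were at Ubr4 on chromosome 4 (position 139380394, 9110 reads), Armc6 on chromosome 8 (70234427, 9081 reads), Ranbp3 on chromosome 17 (56673204, 8534 reads), Mrpl32 on chromosome 13 (14613099, 8280.3 reads), Safb2 on chromosome 17 (56584793, 7685 reads), Txnl4a on chromosome 18 (80206799, 7454 reads) and Xpo5 on chromosome 17 (46202728, 7367 reads). Ehmt1 had its event on chromosome 2 at 24919698, and the Upf1 events were on chromosome 8 at 70353436 and 70353351. Armc6 and the weaker Upf1 event were inside the gene span, and the rest lay outside it by 13 to 265 bp. Ubr4 encodes a ubiquitin ligase, Mrpl32 a mitochondrial ribosomal protein and Xpo5 the nuclear exporter of microRNA precursors. The caller assigned a k-mer to 9 of these 10 events, and Ranbp3 was the exception. The share near a gene end was 60.6% among events with −log10 q of 10 or more and 68.1% among events of 50 reads or more.

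A short sequence resembling the NRF1 site marked most events. The event caller had assigned a k-mer to 12552 events, 66.5% (65.9 to 67.2), drawn from 18 distinct sequences of 7 bases. CTGCGCA was the most frequent, at 2928 events, followed by GCGCAGG at 2223 and GCGCATG, which is part of the palindromic consensus GCGCATGCGC, at 1789. Events with GCGCATG had a median of 64.3 reads, against 21 for the 10763 events with another k-mer (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). Events are not independent replicates, and the caller learned the k-mers from these same events.

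Events with a k-mer were near a gene end in 61.1% of cases and events without one in 32.2%. The odds ratio was 3.32 (3.11 to 3.54). All 18 k-mers contain a CpG dinucleotide. How often they occur near gene ends without an event was not tested, so the odds ratio has no background of sequence to set it against. GGTGCGC, assigned to 366 events, stood apart from the other k-mers and was chosen after its values were seen. It was near a gene end in 18.3% of its events, against 62.4% for the others (odds ratio 0.135, 0.103 to 0.176), with a median of 10 reads. By rank, the k-mer share was 43% (33.7 to 52.8) in the first 100 events and 83.3% (79.3 to 86.6) in ranks 101 to 500.

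**Figure D1:**
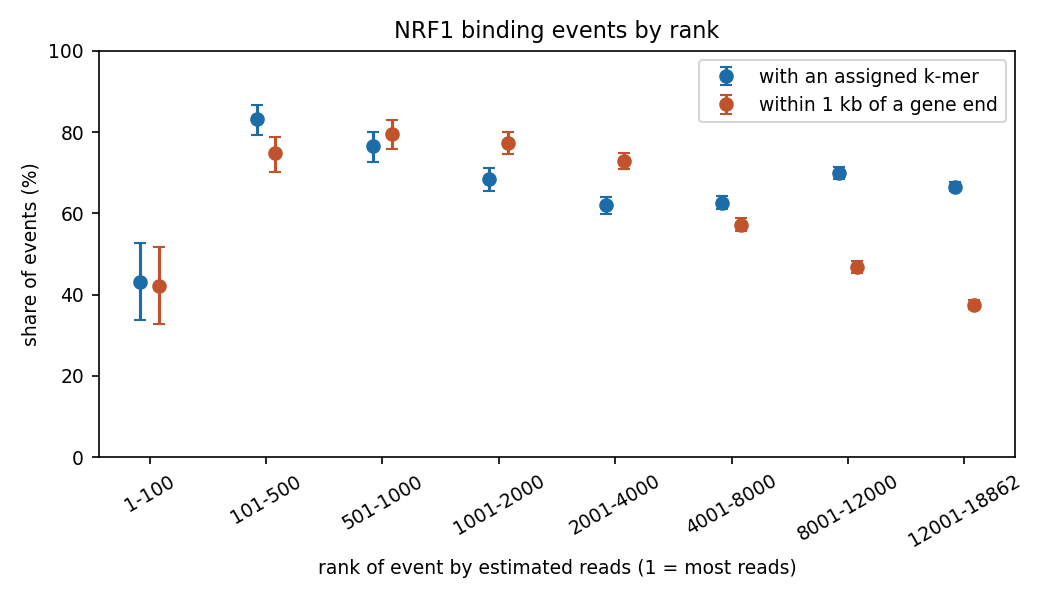
Share of NRF1 events with an assigned k-mer (blue) and within 1 kb of a gene end (orange), in %, by rank of the event on estimated reads; bars are 95% Wilson intervals. The first 100 events have the lowest k-mer share, 43%, and the share near a gene end falls from 79.6% in ranks 501 to 1000 to 37.5% in the last bin.

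Many of the strongest events came from 2 dense clusters. On chromosome 2, 11 events between 98662285 and 98667127 held 1210436 reads, and on chromosome 9, 31 events between 3000573 and 3037399 held 569588 reads. These 42 events took 32.2% of all reads in events, and 0 of them had a k-mer. Leaving them out moved the share near a gene end to 51.6%.

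The 4 mitochondrial gene lists, cytosolic ribosomal proteins, tRNA synthetases and the spliceosome core had NRF1 events more often than other protein-coding genes, while the proteasome and DNA replication did not pass the test. Of 16 lists fixed before the data were examined, 7 were higher, 2 were lower and 7 were not called (two-sided Fisher's exact test, Benjamini-Hochberg over the 16 lists). The share was highest in OXPHOS complex I, the NADH dehydrogenase of the respiratory chain, where 23 of 36 genes had an event within 1 kb of an end (63.9%, 47.6 to 77.5, exact adjusted p = 0.000125). Over all 21900 protein-coding genes, 6139 had an event, 28.0%. Genes that share a promoter share events, so members are not fully independent.

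Within complex I the strongest events were at Ndufb10 (2109 reads), Ndufa6 (1515 reads) and Ndufs6 (1453 reads), while Ndufa1 and Ndufa2 had none. Complexes II to V had events at 16 of 35 genes (45.7%, exact adjusted p = 0.0428), led by Sdha, a subunit of succinate dehydrogenase, with 2196 reads, Uqcrc1 with 2187 reads and Cox6a1 with 1162 reads, and Atp5a1 and Atp5b had none. This call was lost without the genes on chromosomes 2 and 9 (46.4% against 29.2% of other genes, exact adjusted p = 0.0951), without Olfr genes (45.7% against 29.5%, 0.0738) and with only events that have a k-mer (40% against 26.5%, 0.134). It held at −log10 q of 10 or more (40% against 19.4%, exact adjusted p = 0.0273) and at 50 reads or more (40% against 13.8%, 0.000942). Among genes of mitochondrial DNA and import, 14 of 28 had an event (50.0%, exact adjusted p = 0.0363). Polrmt, the mitochondrial RNA polymerase, led with 1473 reads, then Hspa9 with 943 and Timm13 with 604, and Mterf1a and Mterf4 had none. The mitochondrial ribosome list reached 21 of 38 genes (55.3%, exact adjusted p = 0.00231), with Mrpl9 at 1185 reads, Mrpl14 at 754 and Mrps18b at 699, and no event at Mrpl1 or Mrpl11.

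Cytosolic ribosomal protein genes had events at 22 of 40 members (55.0%, exact adjusted p = 0.00231), with Rps12 at 967 reads and Rpl14 at 628 reads, and none at Rpl12 or Rpl13. The tRNA synthetases had 11 of 20 (55.0%, exact adjusted p = 0.0261), with Sars at 914, Kars at 696 and Gars at 589 reads and none at Cars or Dars. In the spliceosome core 15 of 28 genes had an event (53.6%, exact adjusted p = 0.0150), led by Snrnp70 with 1972 reads, Sf3a2 with 1926 and U2af1 with 990.3, and Prpf31 and Prpf8 had none.

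Immune cell marker genes had an event in 0 of 24 cases, which allows a share of up to 12.5% (exact adjusted p = 0.00325); Adgre1 and Cd14 were among them. Keratins had 1 of 24 (4.17%, exact adjusted p = 0.0150), a weak event of 11 reads without a k-mer 709 bp from Krt10, with none at Krt1 or Krt12.

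The lists that were not called included the proteasome with 11 of 31 genes (35.5%, exact adjusted p = 0.520), DNA replication with 17 of 40 (42.5%, 0.0825), germline with 10 of 24 (41.7%, 0.248) and early lineage markers with 4 of 24 (16.7%, 0.348). Heme biosynthesis (2 of 8 genes, 25%), pluripotency (7 of 27, 25.9%) and synaptic genes (7 of 24, 29.2%) each had an adjusted p of 1 in the exact test. Single members of these lists still carried strong events. Psma2 of the proteasome shared the 8280.3-read event of its neighbour Mrpl32, and Psma4 had 1454 and Psmc4 1006 reads, with none at Psma6 or Psmb1. Pola2 of the DNA polymerase alpha complex had 3745 reads, Rfc2 1570 and Cdt1 712, with none at Cdc45 or Cdc6. Alas1, the first enzyme of heme synthesis, had 2697 reads against 10 at Cpox and none at Alad or Fech. Zfp281 led the pluripotency list with 1597 reads, ahead of Klf5 with 214 and Sall4 with 28.4, while Dnmt3l and Dppa2 had none. Germline genes with events included Syce1 (1299 reads), Stk31 (773 reads) and Mov10l1 (125 reads), but not Brdt or Dazl. Stx1a, a synaptic SNARE protein, had 1813 reads, Bsn 317 and Syn1 202, and Camk2a and Dlg4 had none. Early lineage markers had only weak events among the named members, at Neurod1 (49 reads), Mesp1 (36.6 reads) and Sox1 (14 reads), and none at Afp or Cdx2.

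Counting only events of 50 reads or more left complex I (44.4%), complexes II to V (40%) and the cytosolic ribosome (32.5%) called, against 13.8% of other genes. The mitochondrial ribosome (23.7%, exact adjusted p = 0.141), mitochondrial DNA and import (25%, 0.141), tRNA synthetases (30%, 0.119) and the spliceosome (28.6%, 0.119) were not called at that limit. Immune markers and keratins each had 0 of 24 there, and a list of that size could not be called lower, since 0 of 24 gives an unadjusted exact p of 0.0669. With −log10 q of 10 or more, mitochondrial DNA and import (35.7%, exact adjusted p = 0.0741), tRNA synthetases (40%, 0.0724) and the spliceosome (35.7%, 0.0741) were not called, against 19.4% of other genes. DNA replication passed the threshold with a window of 5 kb (0.0153) and without chromosomes 2 and 9 (0.0463).

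**Figure D2:**
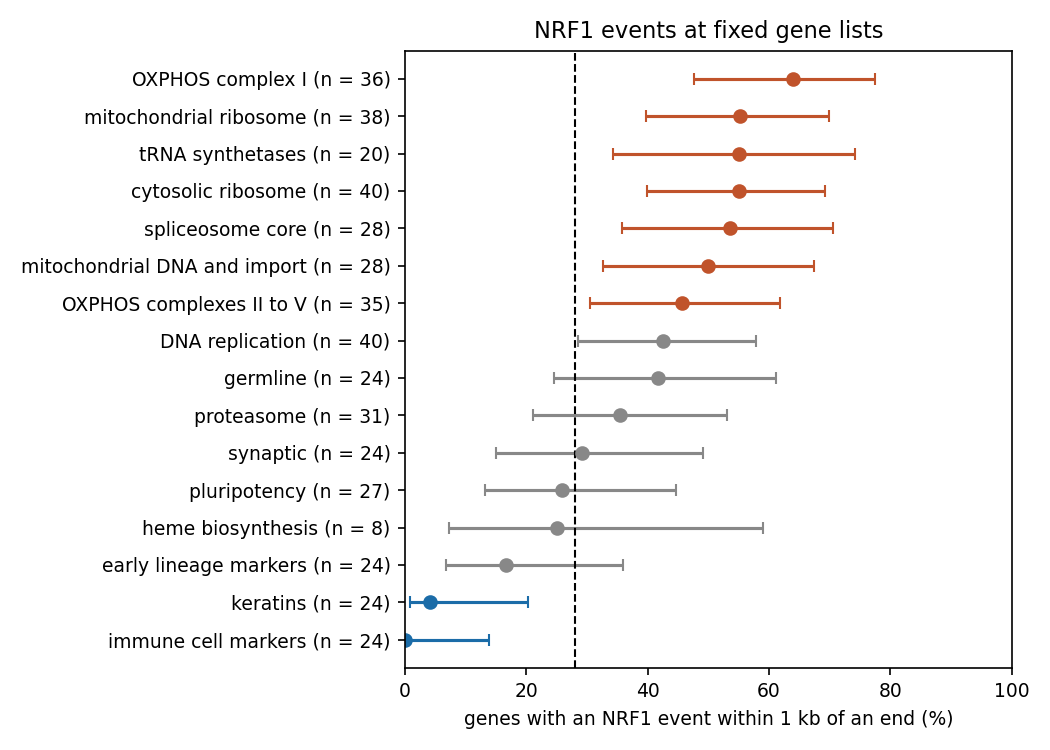
Share of genes in each fixed list with an NRF1 event within 1 kb of either end, in %, with 95% Wilson intervals and list size n; orange is higher and blue lower than other protein-coding genes at an adjusted p under 0.05, and grey is not called. The dashed line is the 28.0% of all protein-coding genes; complex I lies highest at 63.9%.

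Counting all events, genes on chromosomes 2 and 9 had NRF1 events less often than genes on the other autosomes. The share was 20.4% of 2983 genes against 30.4% of 17682 genes, an odds ratio of 0.586 (0.533 to 0.645). Without Olfr genes the odds ratio was 0.672 (0.610 to 0.740), and with events of 50 reads or more, also without Olfr genes, it was 1.01 (0.900 to 1.13). The background that the caller expected per event had a median of 7.7 reads on chromosome 2 and 8 on chromosome 9, and 1.6 to 2.7 reads on the other autosomes. This comparison was chosen after the values were seen.

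**Figure D3:**
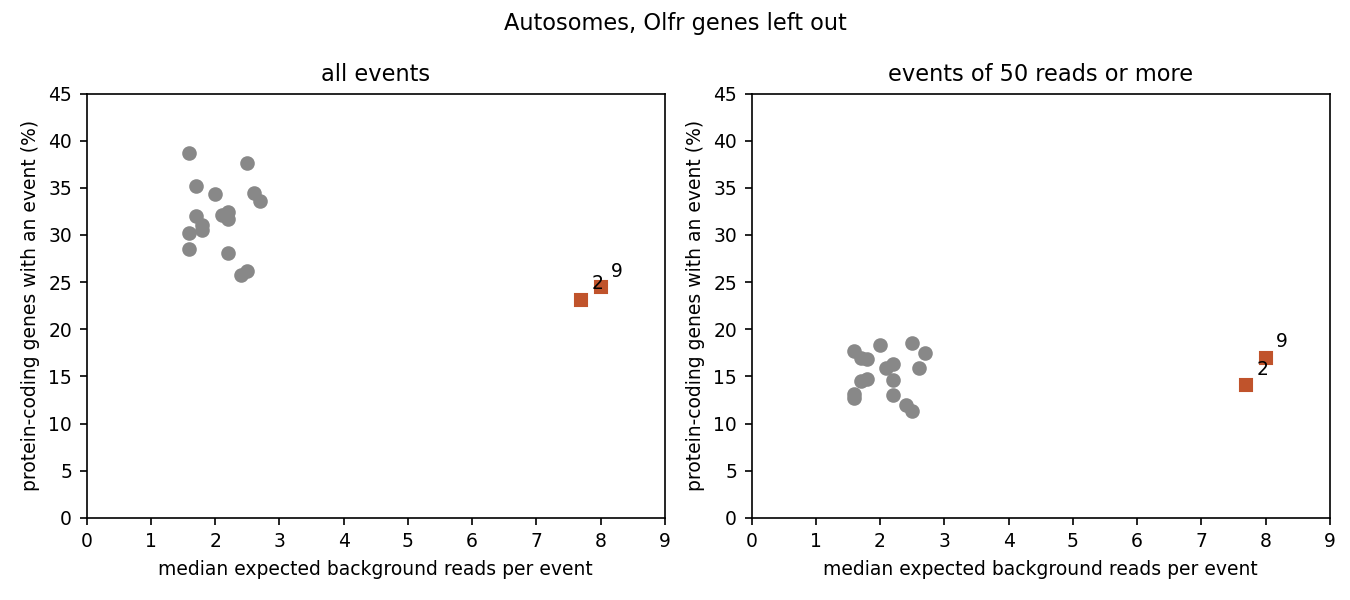
Protein-coding genes with an NRF1 event within 1 kb of an end, in %, against the median expected background reads per event of each autosome, Olfr genes left out; the left panel counts all events and the right panel events of 50 reads or more. Chromosomes 2 and 9 (orange squares) have the highest background, and at 50 reads or more they hold 14% and 17%.

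The SLOT score ranged from 136.7 to 4287 over sequences of 150 to 250 bases. A variable insert between constant flanks was found in 57803 sequences (70.6%), which gave 37481 distinct inserts of 40 to 160 bases. The median insert score was 338.9 (quartiles 261.2 and 501.2), and the highest insert stood 12.6-fold above the median. It was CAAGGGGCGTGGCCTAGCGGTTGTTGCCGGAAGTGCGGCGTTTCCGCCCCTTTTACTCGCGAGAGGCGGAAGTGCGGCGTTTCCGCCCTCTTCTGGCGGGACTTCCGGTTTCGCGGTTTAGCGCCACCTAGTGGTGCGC, with a score of 4287, 65.5% GC and CTCF, ETS and MYB matches. The next 4 scored 3007, 2910, 2850 and 2599, and the 5 lowest scored 145.4, 145.2, 143.9, 143.8 and 140.9. Those next 4 all had a CTCF match and no MYB match, and in each of the 5 lowest MYB was the only match. Each of these highest and lowest inserts was found in 1 sequence. The genomic origin of the inserts, if any, was not analysed here.

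The score followed sequence composition closely. It correlated across inserts with GC content (Pearson r = 0.524 on log2 score, Spearman rho = 0.602) and with the number of CpG dinucleotides (r = 0.661, rho = 0.733; both rho with permutation p = 1e-05, the smallest possible). Counts of the 4096 sequences of 6 bases accounted for 96.4% of the variance of log2 score in 11379 held-out inserts, against 41.3% for single bases. The held-out inserts shared no first 20 bases with the 26102 used for fitting. Near-identical inserts that differ within those 20 bases can still lie on both sides of the split, so these shares may be too high for unrelated sequences. Between 31624 pairs of sequences that differed at 1 base, the median absolute log2 difference was 0.028, against 0.60 for random pairs, and 91.9% of the pairs were within 10%. Whether the score was measured or computed from the sequence is not given in the sources used here. A score computed from the sequence could depend on it this closely. The results on sites below may therefore describe such a function and not a measurement by the assay. Tests on it describe this table, and near-identical inserts are not independent.

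Inserts with a consensus for CTCF, an ETS factor or NRF1 had the highest scores. With CTCF, the insulator zinc finger protein, the median was 807 in 1967 inserts against 328.3 without, a 2.46-fold difference (bootstrap 95% interval 2.38 to 2.51). ETS inserts were 1.96-fold higher (1.78 to 2.15, 198 inserts), and NRF1 inserts 1.77-fold higher (1.74 to 1.80, 2917 inserts). Of 20 motifs tested, 9 were higher and 9 lower (two-sided permutation test of medians, Benjamini-Hochberg over 20 motifs; adjusted p = 2.22e-05 for these 3, the smallest reached here). The remaining 4 motifs, RFX, p53, YY1 and RAR DR5, had under 10 inserts each and were not tested.

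The other consensus sites with higher scores were ZBTB33 (1.35-fold, permutation adjusted p = 8e-05), the orphan nuclear receptor ESRRB (1.20-fold, 0.000236), the E-box (1.12-fold, 2.22e-05), MYB (1.06-fold, 2.22e-05), E2F (1.05-fold, 0.00025) and CREB/ATF (1.03-fold, 0.0346). Lower scores went with FOX (0.656 of the score without, 73 inserts), GATA (0.670, 269 inserts), TEAD (0.693, 148 inserts), OCT4 (0.698, 16 inserts), SOX (0.771, 89 inserts), ZFX (0.809, 47 inserts), AP-1 (0.836, 135 inserts), NFY (0.905, 979 inserts) and KLF/SP (0.944, 959 inserts). The bootstrap interval of ZFX, 0.699 to 1.12, included no difference although its adjusted p was 0.0304. STAT (permutation adjusted p = 0.320) and the partial REST site (0.279) were not called. When inserts of lower and of higher GC content were compared separately, AP-1 turned to higher (log2 difference 0.29) and MYB to lower (-0.034). FOX was no longer called (permutation adjusted p = 0.759). GATA moved from -0.58 to -0.30, TEAD from -0.53 to -0.35 and KLF/SP from -0.084 to -0.14, all still called. OCT4, SOX, STAT and the partial REST site had under 5 inserts in a GC part and were not compared in this way. With 1 insert per shared first 20 bases, 4 motifs lost their call. The log2 difference of OCT4 was -0.48 in 9 inserts, against -0.52 in 16 (permutation adjusted p = 0.0967), and that of NFY -0.11 in 240 inserts, against -0.14 in 979 (permutation adjusted p = 0.0671). ZFX went from -0.31 to -0.07 (permutation adjusted p = 0.687) and KLF/SP from -0.084 to -0.03 (permutation adjusted p = 0.653). The log2 difference of E2F moved from 0.07 to 0.37 with 1 insert per shared first 20 bases and to 0.23 within the GC parts. That of CREB/ATF moved from 0.05 to 0.29 and 0.35. With 1 insert per shared first 20 bases, ZBTB33 moved from 0.43 to 0.76 and the E-box from 0.16 to 0.25. ESRRB moved from 0.27 to 0.67 in the 32 inserts found in 2 or more sequences. In the 4868 inserts found in 2 or more sequences, 8 motifs were not called, each with its direction kept: ZBTB33 (permutation adjusted p = 0.0795), NFY (0.089), MYB (0.261), E2F, KLF/SP and AP-1 (0.305 each), SOX (0.317) and CREB/ATF (0.752).

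**Figure D4:**
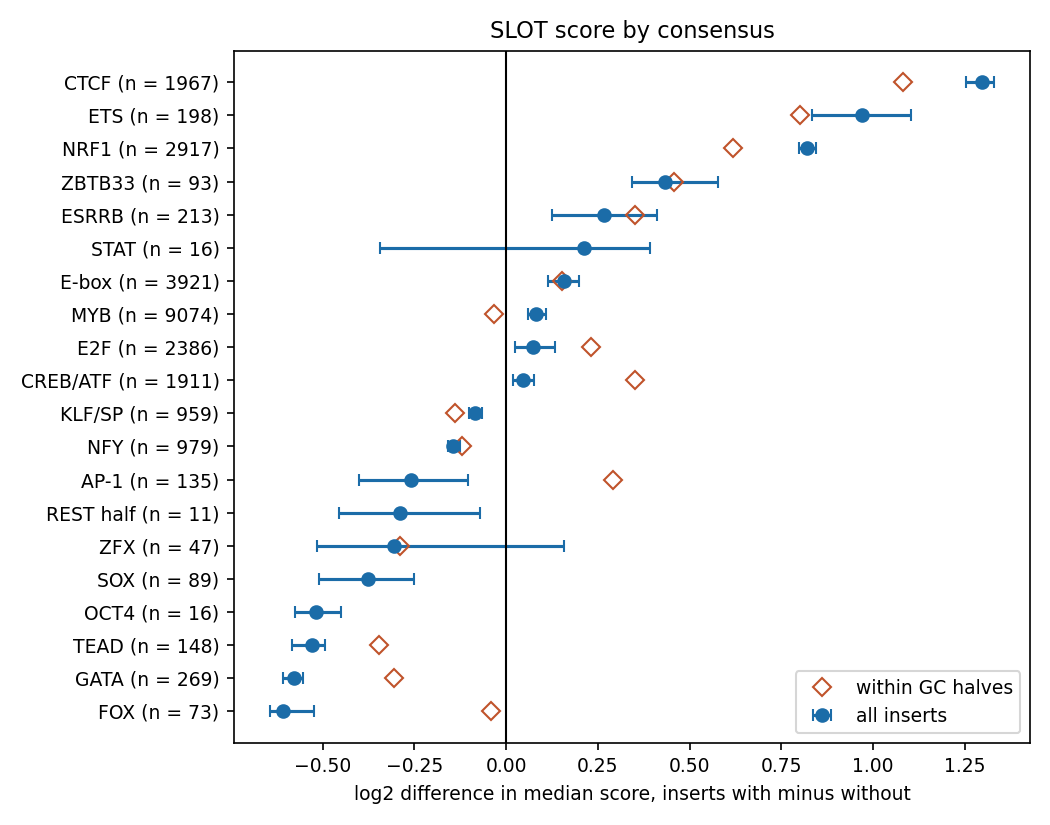
Log2 difference in median SLOT score between inserts with and without each consensus; circles are all inserts with bootstrap 95% intervals and n inserts, and open diamonds are the mean difference within the inserts below and above the median GC content. CTCF lies highest at 1.30, and AP-1 changes side between both.

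More NRF1 sites went with a higher score. The median was 325 in inserts with no NRF1 consensus, 553 with 1 site (2605 inserts), 794 with 2 (271 inserts) and 915 with 3 (41 inserts). Across all tested motifs, the score rose with the number of different consensus sites (Spearman rho = 0.264, Pearson r = 0.297, permutation p of rho = 1e-05, the smallest possible), from 306 in inserts with none to 1026 in 27 inserts with 5. Inserts are not independent replicates. Insert length, 40 to 160 bases, was not held fixed, and a longer insert has room for more sites. The 5 highest inserts had 100 to 139 bases and the 5 lowest 60 to 72. Each NRF1 consensus also contains CpG dinucleotides, whose number correlated with the score (Spearman rho 0.733) and was not held fixed. Whether length or the number of CpG dinucleotides accounts for these rises was not tested.

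**Figure D5:**
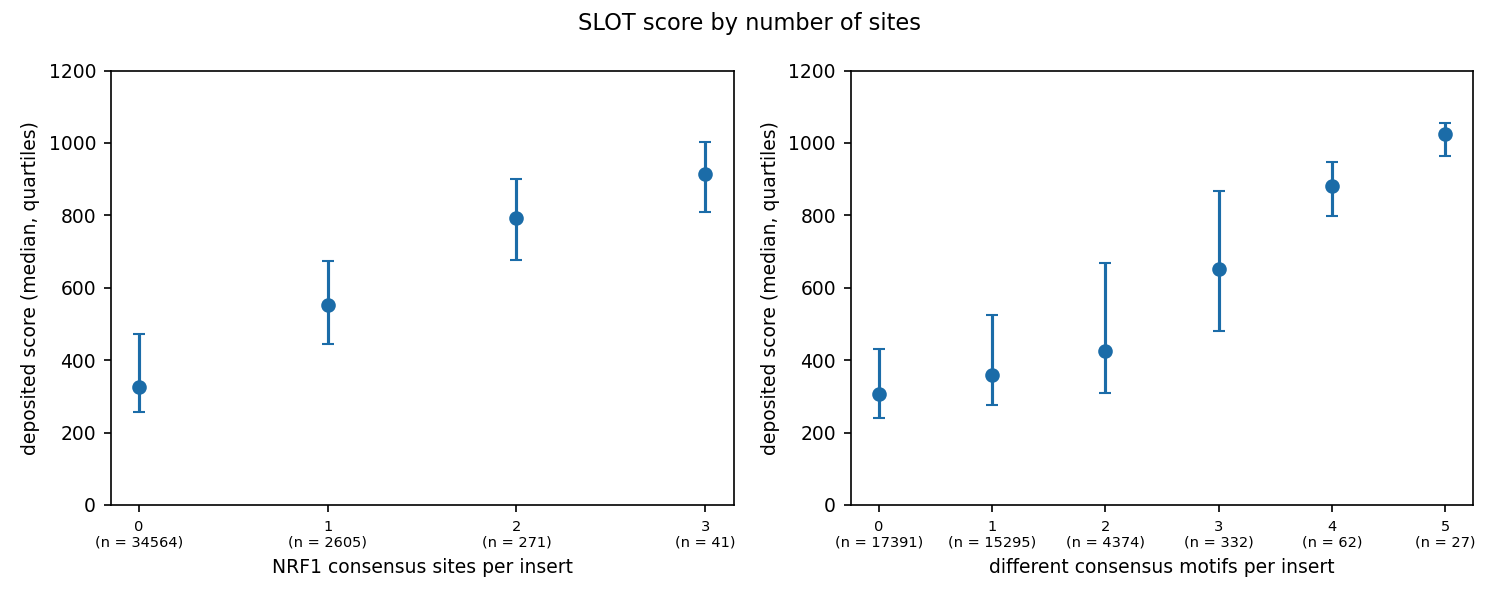
Deposited SLOT score by number of NRF1 consensus sites per insert (left) and by number of different consensus motifs per insert (right); points are medians, bars reach the quartiles and n is the number of inserts. The median rises from 325 to 915 on the left and from 306 to 1026 on the right.

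Where sequences differed at 1 base and in their number of sites for a motif, the median difference put the one with more sites higher for 10 of the 12 motifs with at least 20 such pairs. The sequence with the NRF1 site was higher in 214 of 214 pairs, by a median of 1.18-fold, and with the CTCF site in 146 of 147 pairs, by 1.30-fold. For ETS it was 24 of 27 pairs (1.17-fold) and for CREB/ATF 109 of 111 (1.13-fold). KLF/SP (56 of 69 pairs, 1.08-fold), NFY (38 of 40 pairs, 1.07-fold) and AP-1 (482 of 492 pairs, 1.02-fold) were higher with the site in such pairs. Over all inserts these 3 scored lower, but there sites were counted within the insert alone. In the pairs they were counted over the whole sequence, constant flanks included. Sequences with more AP-1 sites in the pairs covered 389 distinct inserts, against 135 inserts with an AP-1 match. For most of those 389 the site was thus not within the insert, and the comparisons do not cover the same sites. KLF/SP and NFY stayed lower and called by means and within the GC parts, and were not called with 1 insert per shared first 20 bases. AP-1 was lower with 1 insert per shared first 20 bases (log2 difference -0.43, permutation adjusted p = 0.000494), was not called by means (permutation adjusted p = 0.264) and was higher within the GC parts. E2F (99 of 118 pairs, 1.03-fold), the E-box (141 of 190, 1.04-fold) and MYB (442 of 611, 1.01-fold) were higher with the site. ZFX (11 of 30 pairs higher, 0.984-fold) and GATA (11 of 34, 0.994-fold) went the other way, and the bootstrap interval of the log2 difference of ZFX, -0.05 to 0.01, included no difference. Over all single-base pairs the median absolute log2 difference was 0.028. The median differences of AP-1 (0.025), MYB (0.015), ZFX (-0.024) and GATA (-0.009) were smaller in size than that. Base changes outside a site were not compared, so the change in composition was not held fixed. Pairs of related sequences are not independent, and the bootstrap resampled pairs singly.

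The read count per event between nodox, dox, sr3 and sr8 was not compared, because the event table has no column per condition. A comparison of the SLOT score with a predicted or genomic accessibility was not made, since the table analysed holds 1 value per sequence.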

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

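The event table lists 3 events on the mitochondrial genome, with 581.1 estimated reads in all. They are counted among the 18862 events, and the 13 protein-coding genes of that genome among the 21900, but no comparison was about them. They are given here because the reads exceed the limit that a count of 0 allows and there was no control library to set them against. Their reads were 135.1, 279 and 167, against an expected background of 88.8 at each, and 0 of the 3 had an assigned k-mer. No explanation was tested.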

How the results depend on the processing

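Alternatives that count events of 50 reads or more, events with a k-mer, or leave out clusters, chromosomes or Olfr genes, and those on repeated or related inserts, were chosen after seeing the data. The share of NRF1 events near a gene end was 51.4% and moved to 44.2% with a window of 500 bp, 66.8% with 5 kb, 46.1% for protein-coding genes alone, 60.6% at −log10 q of 10 or more and 68.1% at 50 reads or more; the first 3 follow from a smaller or larger target, and for the last 2 the cause was not tested. The k-mer share moved from 66.5% to 64.8% at 50 reads or more; the cause was not tested. The number of lists called fell from 9 to 3 at 50 reads or more, where fewer genes carry an event, and was 6 to 10 under the others. The number of consensus motifs called fell from 18 of 20 tested to 7 of 15 in inserts found in 2 or more sequences. There 4868 of 37481 inserts were left, and the other motifs could not be tested. The number was 17 of 20 by means, 15 of 16 within the GC parts and 14 of 19 with 1 insert per shared first 20 bases. Within the inserts of lower and higher GC content, AP-1 reversed to a log2 difference of 0.29 and MYB to -0.034; the cause was not tested. Of 112 list values 92 kept direction and side of the threshold, 12 lost the call, 2 gained it and 6 reversed, all in lists not called in either setting. Synaptic genes reversed to 16.7% against 19.5% of other genes at −log10 q of 10 or more, 25% against 29.2% without chromosomes 2 and 9, and 29.17% against 29.51% without Olfr genes. Heme biosynthesis reversed to 25% against 24.6% with a window of 500 bp and 50% against 37.0% with 5 kb, and pluripotency to 37.04% against 36.99% with 5 kb. Of 70 motif values 54 kept both, 14 lost the call and 2 reversed. The correlation with the number of different sites stayed between 0.264 and 0.293, and the median SLOT score between 337.8 and 339.8. The depth minimums, pseudocounts, consensus windows, promoter CpG model and scaling of conditions that were planned were not run, because the tables used have no reads per sequence and no column per condition, and no genome was used. Depth limits of the SLOT score are unknown. Events down to 5 reads are listed, but none below 15.1 reads on chromosome 2 or 15.2 on chromosome 9. A missing event at a gene thus shows only that none was called at this depth and above the limit of its chromosome.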

Other observations

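The comparison of mitochondrial with other housekeeping lists was chosen only after the list results were seen, and so was the grouping of k-mers that share bases; the tests of Olfr genes, background, GC content, the slope and the k-mer percentile were written down before their results were seen, on patterns already noticed.

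The top 1% of inserts by SLOT score, 375 inserts, was mostly made of inserts with a CTCF site. CTCF was present in 80.5% (76.2 to 84.2) of them, against 5.25% of all inserts. E2F was present in 24.5% against 6.37%, ETS in 4% (15 inserts) against 0.528% and ZBTB33 in 1.33% (5 inserts) against 0.248%. NRF1 was present in 3.73% (2.24 to 6.17), against 7.78% of all inserts, although NRF1 inserts had a higher median score. NFY was present in 0 of the 375 (below 0.8%, the limit that 3 inserts allow), against 2.61% of all inserts.

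Genes on chromosomes 2 and 9 had fewer NRF1 events than genes on other autosomes (odds ratio 0.586, 0.533 to 0.645). Olfactory receptor genes, which are many on both, are not the whole cause, since without Olfr genes the odds ratio was 0.672 (0.610 to 0.740). A background raised by the read-rich clusters on both chromosomes may hide weak events there. The weakest listed event had 15.1 reads on chromosome 2 and 15.2 on chromosome 9, against 5 to 7.1 on the other autosomes. Whether the clusters raised that limit was not tested. With Olfr genes left out as well, among events of 50 reads or more the shares were 15.3% and 15.2%, an odds ratio of 1.01 (0.900 to 1.13), above the 0.672 for all events without Olfr genes, as that explanation requires. A biological difference between chromosomes was not tested.

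Mitochondrial lists had events more often than protein-coding genes at large, and a candidate explanation is that housekeeping promoters in general carry NRF1 events. Pooled mitochondrial lists had events at 74 of 137 genes (54.0%) and pooled ribosome, proteasome, replication, tRNA synthetase and spliceosome lists at 76 of 159 (47.8%). The odds ratio was 1.28 (0.811 to 2.03; Fisher's exact test, two-sided, p = 0.296). The interval allows both no difference and a doubling of the odds, so these lists are too small to decide.

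Inserts with the NRF1 consensus were richer in GC (median 63.9%) than those without (58.9%), so GC content could account for their higher SLOT score. Within inserts below and above the median GC content the mean log2 difference was 0.62 (0.59 to 0.65), against 0.82 over all inserts. GC content may thus account for part of the difference, and a difference remained within these parts. GC content still varied within each part. The number of CpG dinucleotides, which correlated more closely with the score (Spearman rho 0.733 against 0.602), was not held fixed. The comparison therefore cannot decide whether composition accounts for all of the difference. The score may itself be computed from sequence, which these tables do not settle.

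One hypothesis on the score was that an NRF1 site acts by a fixed factor and not by a fixed amount. Over 214 pairs of sequences from 131 groups of related inserts, the slope of log2 score gain on the log2 score without the site was 0.94 (0.69 to 1.20, groups resampled). A fixed factor gives a slope of 1 and a fixed amount a slope of 0. The interval included 1 and excluded 0, as a factor requires, in this score. A score computed from the sequence could have such a factor built in. The score without the site also enters both values compared. The slope therefore describes this score and cannot decide how NRF1 sites act. The medians of inserts with 0, 1, 2 and 3 sites, 325, 553, 794 and 915, did not rise by a constant factor. Those inserts also differ in the rest of their sequence, so these medians do not test it. Another hypothesis was that the k-mers called under NRF1 events mark higher SLOT scores beyond their GC and CpG content. The median percentile of the 18 k-mers among sequences of 7 bases with the same GC and CpG count was 69.9, and 4.13% of 10000 random lists reached it. All 18 are linked by shared stretches of 5 bases and fall in 1 group, so the random lists understate chance, and with 1 group the comparison cannot decide (31.3% of random draws were as high).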
